A study of Rattus norvegicus with 10 samples.

How the data were processed

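Round spermatids, the haploid germ cells that follow meiosis in the testis, were taken from Brown Norway rats of 2 ages, per the labels: 4 to 6 months (young, 5 samples) and 18 to 20 months (aged, 5 samples). Per the labels' protocols, germ cells were separated by STA-PUT, which sorts cells of a testis suspension by their sedimentation speed, RNA was purified with a column kit, and 1.3 ug of total RNA per sample went into a SMARTer mRNA library. The labels do not say whether each sample came from its own animal, so the p-values measure the spread between these samples.

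The deposited files give FPKM values, fragment counts scaled to gene length and to the library's total, 1 file per sample, with the same 32545 genes in each, per the file headers. The submitters' processing notes name HISAT2 2.0.5 and featureCounts 1.5.0-p3; their settings, the strand setting and the genome build are not given in the sources used here. Coordinates below are those of the files, with the build not given in the sources used here, and gene names and lengths are also those of the files. No reference sequence was used, so GC content was not checked. The labels name no batch.

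Whole fragments were recovered from each FPKM value, its gene length and the smallest step of its sample. Within a tolerance of 0.001, 100% of the values above 0 came out whole in every sample. The recovered totals were 14488222 to 18203223 fragments per sample. The denominator behind the FPKM values was 0.966 to 1.03 times that total, with a geometric mean of 1.00 over samples. The authors' values thus carry a small rescaling between samples, whose method is not given in the sources used here. Median-of-ratios scaling gave the same 1544 genes at an unadjusted p under 0.05 as the deposited values. The deposited values were therefore already level by that measure. A value of 1 FPKM over 1 kilobase stands for 14.6 to 18.6 fragments. Genes on overlapping positions, on opposite strands, or with near-identical copies cannot be told apart where counting splits or drops shared fragments.

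The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), over the 12985 genes with a mean of at least 1 FPKM across the 10 samples, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are therefore on the log2(FPKM + 1) scale, which understates changes of low genes. Because the deposited unit is FPKM, the count model planned for files of counts was not run; limma's voom on the recovered fragments served as the alternative that models depth.

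Before the data were examined, 30 gene lists were fixed, holding 1092 genes, of which 999 matched a name in the files. Of these, 28 lists had at least 5 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists; the same test with an estimated correlation, and fry, served as alternatives. A list score per library is the mean over members of log2(FPKM + 1) minus each gene's mean over the 10 libraries. Scores were compared by an exact permutation test over the 252 ordered splits, two-sided. Genes on chromosome X were tested against all other tested genes with camera, and their median was set against that of the autosomes. The spread between samples was compared as the share of tested genes with a larger SD in the aged group, with an exact permutation test.

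Genes named in the text were chosen by a rule fixed before the data were examined: the 10 with the largest change per direction among those past the threshold with at least 5 FPKM in a group, an assigned symbol and no overlap between the groups, then members of each list: its first 2 tested members, and up to 4 that pass, of which there were none. As no gene passed, the rule's fallback to the smallest unadjusted p was used, keeping the other criteria. A result of this rule that concerns an item withheld for evaluation is not reported here. Further genes are named as chosen after their values were seen.

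Alternatives fixed in advance were a pseudocount of 0.1, filters at 0.1 and 5 FPKM and none, median-of-ratios, TPM and quantile scaling, protein-coding genes only, robust eBayes, sample weights, a replicate block, a minimum change of 1.5-fold, voom, and leaving out each sample in turn. Each list was tested by itself in advance only under the block, the pseudocount, median-of-ratios scaling, the other set tests and the leave-outs, and under the rest after seeing the data. Chosen after seeing the data were also the fits without the aged replicates 1 and 2 together, with a score of markers of other cell types as a covariate, with a trend on gene length and level removed per library, and, for chromosome X and the scores of the double-strand break and mismatch repair and piRNA lists, with a stage score as a covariate.

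The tests were checked on simulated data drawn from the real means, library sizes and spreads, with 200 genes changed. Over 12990 simulated genes, limma recovered 64.2% of the 1.5-fold changes, 83.6% of the 2-fold changes and 96.7% of the 4-fold changes of this comparison, with 15 false calls; voom recovered 67.2%, 83.6% and 96.7%, with 8 false calls. A planted shift of 0.2 in the ribosomal protein list gave an adjusted p of 8.21e-28 by camera, and none of the other 28 lists tested there passed. The simulated genes varied independently of each other, which the genes of real libraries do not. The 200 changed genes were drawn at random among those tested, so these shares do not hold for genes of wide spread. The 15 false calls of limma stood beside 43, 56 and 59 recovered genes at the 3 fold changes. Libraries of a group were checked for duplicates by a chi-square test of the recovered fragments, which gave 4.17 to 15.4 per degree of freedom for each pair, so none was taken as a repeat. Python 3.11.15 with matplotlib 3.10.9 drew the plots.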

Results

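Messenger RNA of round spermatids was measured in 5 young and 5 aged Brown Norway rat samples to ask how age changes gene expression in these cells. The recovered depth was 14488222 to 17401744 fragments per library in the young group and 15992576 to 18203223 in the aged group. At least 1 FPKM was reached by 12732 to 12907 genes per young library and by 12703 to 13576 per aged library. Spermatid genes were abundant in both groups: Prm1, which encodes a protamine that packs sperm DNA, averaged 12150 ± 3121 FPKM in young and 10130 ± 1373 FPKM in aged samples (SD, n = 5), and Tnp1, a transition protein that precedes it, 5358 ± 812 and 5136 ± 1008 FPKM.

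No gene passed the threshold between aged and young round spermatids. Of the genes named by rank, Tpm2, a tropomyosin, averaged 2.98 ± 0.613 FPKM in young and 8.47 ± 4.43 FPKM in aged samples (SD, n = 5), a log2 difference of 1.16 (SE 0.23). Tpm2 stood at 16.29 FPKM in aged replicate 2 and at 5.457 to 7.23 FPKM in the other aged libraries. It is a member of the peritubular and stromal list, markers of other testis cells described below. Son, a splicing cofactor, averaged 65.5 ± 2.54 FPKM in young and 55.8 ± 2.83 FPKM in aged samples, a log2 difference of -0.23 (SE 0.05).

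Of the 12985 genes tested with limma, 0 passed and the smallest adjusted p was 0.281; voom also called 0. At an unadjusted p under 0.05 there were 1544 genes against 649 that chance gives, 719 higher and 825 lower in aged samples, and 1536 with voom. The split depended on the scaling: 46.6% of these genes were higher with the deposited values, 61.2% after TPM scaling and 62.8% with voom. The groups did not overlap for 338 genes, 2.6% of those tested, where chance gives 0.79%; of these 177 were higher and 161 lower. A change of at least 2-fold was fitted for 101 genes, 81 of them higher in aged samples. A gene passed in each of 2 fits that left out a sample, both chosen here after their values were seen. Without young replicate 1 it was SNORD14 (adjusted p = 0.000155), a small nucleolar RNA listed at 0 in every aged library and in young replicate 1, the library left out. SNORD14 stood at only 2.234 to 3.595 FPKM in the other young libraries, low values of the kind that depth limits most. Without young replicate 2 the gene that passed was AC117925.6 (adjusted p = 0.0275). Without aged replicates 1 and 2, 972 genes had an unadjusted p under 0.05 and 0 passed.

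The 20 genes named by rank had adjusted p values of 0.319. Tmem167a (ENSRNOG00000016686, chromosome 2, 18937458 to 18943561, plus strand) averaged 15.9 ± 1.20 FPKM in young and 19.7 ± 0.781 FPKM in aged samples, a log2 difference of 0.30 (SE 0.06). Pin4 (ENSRNOG00000050051, chromosome X, 72004482 to 72011664, plus strand), a prolyl isomerase, averaged 11.1 ± 0.614 and 14.8 ± 1.64 FPKM, and Nkap, also X-linked, 3.92 ± 0.560 and 5.31 ± 0.257 FPKM. Rala, a small GTPase, and Ring1, a Polycomb protein, differed by 0.23 and 0.30 on the log2 scale. Vim, an intermediate filament (ENSRNOG00000018087, chromosome 17, 80882666 to 80891212, plus strand) averaged 7.14 ± 1.62 and 19.07 ± 11.5 FPKM. It stood at 39.42 FPKM in aged replicate 2 and at 12.7 to 16.27 FPKM in the other aged libraries. Among the higher genes named by rank, Vim is in the Sertoli cell list, Tpm2 and Tagln in the peritubular list and Nr4a1 in the immediate-early list. On the lower side, Nf1 (ENSRNOG00000013780, chromosome 10, 66690133 to 66928903, plus strand) averaged 11.4 ± 0.634 FPKM in young and 9.44 ± 0.318 FPKM in aged samples. Wdr95, Lsm14b and Lctl had the lowest log2 differences of this group, at -0.39, -0.40 and -0.36. Gpr108, Cpd, Vps13a, Ftsj3 and Tbc1d13 lay between -0.28 and -0.19. The lower genes were 1319 bp (Lsm14b) to 9326 bp (Nf1) long and the higher ones 216 bp (Tmem167a) to 2660 bp (Nr4a1). The median over all tested genes was 1886 bp. The trend with gene length described below may thus have a share in these differences. Each of the 20 genes named by rank had 5 aged values outside the range of the 5 young values. The rule for naming required this, so it is no separate support.

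Markers of other testis cells were higher in the aged spermatid libraries with a preset correlation, a call that an estimated correlation did not keep (adjusted p = 0.573 for the peritubular, Leydig cell, Sertoli cell and macrophage lists). The peritubular and stromal list, contractile and matrix genes of the tubule wall, had 16 of 17 tested members higher, with a median log2 difference of 0.83. Acta2, smooth muscle actin, averaged 28.6 ± 5.73 FPKM in young and 50.6 ± 21.1 FPKM in aged samples (SD, n = 5). All 7 tested Leydig cell members were higher: Insl3, a Leydig cell hormone, averaged 3.31 ± 0.754 and 29.7 ± 34.2 FPKM, and Cyp17a1, an enzyme of androgen synthesis, 0.832 ± 0.393 and 9.28 ± 9.95 FPKM. Aged replicate 2 carried these aged means, which were 15.5 FPKM for Insl3 and 5.16 FPKM for Cyp17a1 without it, and 8.24 and 3.10 FPKM without both aged replicates 1 and 2. Of 18 macrophage members 16 were higher, with a median of 0.78, and of 17 Sertoli cell members 15, with a median of 0.28.

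By camera with the preset correlation, the adjusted p was 2.37e-10 for the peritubular list, 5.27e-05 for the macrophage list, 0.00096 for the Sertoli cell list and 0.0018 for the Leydig cell list. Over all genes no member passed. Adjusted over the list alone, 10 peritubular, 8 macrophage, 2 Leydig cell and 1 Sertoli cell members passed. The macrophage members went both ways: Apoe, C1qa, C1qb, Ctss, Fcer1g and Tyrobp rose and Adgre1 and Cx3cr1 fell. Clu, a Sertoli cell secreted protein, averaged 15.8 ± 1.82 and 29.5 ± 26.2 FPKM, and Wt1 1.87 ± 0.409 and 1.95 ± 0.407 FPKM. Cd74, of antigen presentation, averaged 2.33 ± 1.32 and 3.43 ± 3.08 FPKM and Cd163, a scavenger receptor of macrophages, 0.576 ± 0.337 and 3.13 ± 3.80 FPKM. Without aged replicate 2 the aged means were 17.9 FPKM for Clu, 2.16 FPKM for Cd74, below the young mean, and 1.503 FPKM for Cd163, which was 0.879 FPKM without both aged replicates 1 and 2. The macrophage call was lost over genes with a mean of at least 5 FPKM (adjusted p = 0.814). The lymphocyte list did not pass (adjusted p = 0.872, 2 of 5 members higher), and its median of -0.02 and mean of 0.16 differed in sign. Endothelial and erythroid lists had too few tested members.

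The score of the somatic lists together was highest in aged replicate 2 (1.21), followed by aged replicate 1 (0.43), while the other aged libraries lay between -0.15 and 0.00 and the young libraries between -0.46 and -0.06. The groups differed by 0.59 (exact permutation p = 0.0159). Without aged replicates 1 and 2 the 4 lists still passed with the preset correlation, with adjusted p values of 5.49e-07 for the peritubular, 0.0126 for the Leydig cell, 0.0126 for the macrophage and 0.0483 for the Sertoli cell list. Their medians were smaller: 0.27 against 0.83 for the peritubular, 0.12 against 0.20 for the Leydig cell, 0.22 against 0.78 for the macrophage and 0.05 against 0.28 for the Sertoli cell list. With this score as a covariate none of the 4 lists passed (0.0742 to 0.502), as the score is made of members of the somatic lists.

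**Figure D1:**
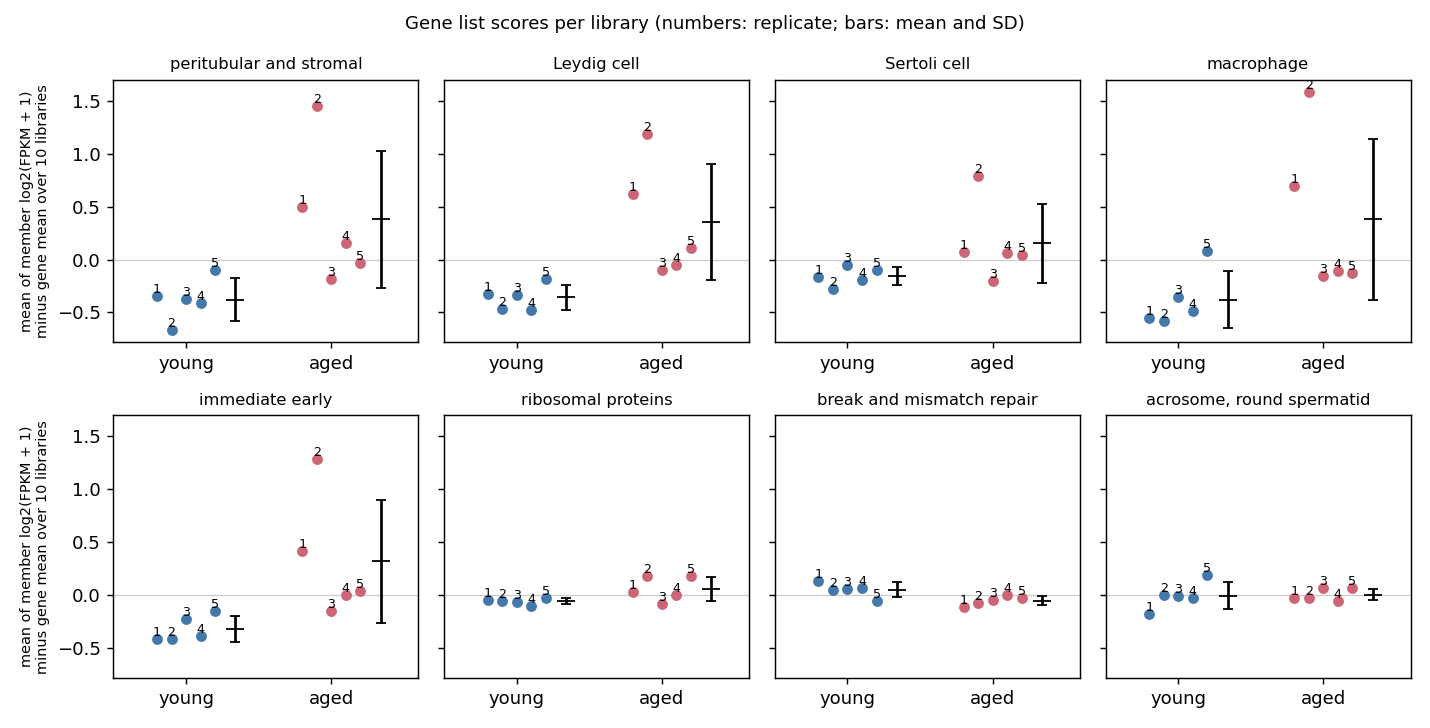
Gene list scores of the 10 libraries for 8 fixed lists, as the mean over members of log2(FPKM + 1) minus each gene's mean (y axis), for young and aged samples (x axis), with the replicate number beside each point and bars for the mean and SD. Aged replicate 2 is the highest library for the peritubular list (1.45), the Leydig cell list (1.19), the macrophage list (1.59) and the immediate-early list (1.29).

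Immediate-early genes respond within minutes to stimulation or to cell dissociation. As a list they were also higher in the aged libraries by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.573). Of 17 tested members 16 were higher, with a median log2 difference of 0.64. Fos averaged 6.47 ± 2.36 FPKM in young and 19.9 ± 18.5 FPKM in aged samples (SD, n = 5), Jun 4.52 ± 0.403 and 9.70 ± 7.35 FPKM, and Nr4a1 8.41 ± 1.16 and 12.3 ± 2.05 FPKM. Without aged replicate 2 the aged mean of Fos was 11.75 FPKM. The camera adjusted p was 2.71e-09, and 0.573 with an estimated correlation. Adjusted over the list alone 8 members passed, and over all genes 0. The antioxidant list was higher as well (adjusted p = 0.0024, and 0.573 with an estimated correlation), with 23 of 39 members higher and a median of 0.06; Sod1 averaged 171 ± 14.5 and 196 ± 18.6 FPKM and Gpx4, a peroxidase that sperm need, 32.8 ± 3.497 and 34.6 ± 4.95 FPKM. The inflammation and interferon list had an adjusted p of 0.0386, and 0.618 with an estimated correlation, with 7 of 11 members higher; Il18 averaged 2.63 ± 0.598 and 2.05 ± 0.503 FPKM. Its call was lost without young replicate 2 (0.0746) or 3 (0.0869), or without aged replicate 1 (0.0567), 2 (0.121) or 4 (0.0509). The scores of these 3 lists were highest in aged replicate 2, at 1.29, 0.54 and 0.76. Without aged replicates 1 and 2 the medians were 0.25 for the immediate-early list (adjusted p = 5.49e-07), 0.02 for the antioxidant list (0.0205) and 0.01 for the inflammation list (0.310). With the somatic score as a covariate none of the 3 passed (0.442, 0.964 and 0.623), and the inflammation call was also lost after TPM (0.0525) or quantile scaling (0.0660) and with voom (0.0597).

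Genes of double-strand break and mismatch repair were lower in the aged libraries by camera with the preset correlation (adjusted p = 0.0016), but not with an estimated correlation (0.573) or with the somatic score as a covariate (0.0742). Of 32 tested members 28 were lower, with a median log2 difference of -0.104, and of -0.085 with that covariate. Atm and Atr, kinases that signal DNA damage, averaged 5.02 ± 0.626 and 21.8 ± 1.71 FPKM in young and 4.04 ± 0.269 and 18.5 ± 1.24 FPKM in aged samples (SD, n = 5). Over all genes or adjusted over the list alone, 0 members passed. The list score differed by -0.10 between the groups and that of the meiosis list, markers of spermatocytes, by -0.08. The excision repair lists did not pass, and no test compared them with this list: base excision repair had 9 of 17 members higher (adjusted p = 0.212; Ogg1 2.41 ± 0.288 and 2.32 ± 0.461 FPKM, Apex1 86.0 ± 9.03 and 92.9 ± 10.3 FPKM) and nucleotide excision repair 17 of 23 members lower, with a median of -0.07 (adjusted p = 0.212).

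Genes of the piRNA pathway, which silences transposons in germ cells, had 22 of 27 members lower, with a median of -0.08 (adjusted p = 0.0329, and 0.618 with an estimated correlation). Piwil1 averaged 13.0 ± 2.01 FPKM in young and 11.7 ± 2.70 FPKM in aged samples and Ddx4 172 ± 5.42 and 169 ± 6.88 FPKM (SD, n = 5). This call was lost without young replicate 1 (0.109) or 3 (0.0535), without aged replicate 1 (0.239) or 2 (0.101), and without both aged replicates 1 and 2 (0.900). It was also lost over genes with a mean of at least 5 FPKM (0.112), after TPM (0.0525) or quantile scaling (0.0582), with sample weights (0.0560) and with the somatic score as a covariate (0.964). The libraries with the lowest piRNA scores, aged replicates 1, 2 and 3 (-0.19, -0.12 and -0.06), also had the lowest meiosis scores (-0.12, -0.10 and -0.12). Axoneme and motility genes had 37 of 59 members lower, with a median of -0.05 (adjusted p = 0.0386, and 0.669 with an estimated correlation). Dnah1, a dynein heavy chain of the flagellum, averaged 13.8 ± 1.11 and 11.7 ± 1.10 FPKM, and Catsper1, a sperm calcium channel, 42.1 ± 5.17 and 42.2 ± 4.53 FPKM. This call was lost without young replicate 2 (0.0746), 3 (0.0712) or 4 (0.134), without aged replicate 2 (0.129), 4 (0.0781) or 5 (0.0611), and without both aged replicates 1 and 2 (0.191). It was also lost over genes with a mean of at least 5 FPKM (0.109), after TPM (0.131) or quantile scaling (0.0830), with voom (0.147) and with the somatic score as a covariate (0.964). Neither list had a member that passed over all genes or adjusted over the list alone.

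Germ cell stage lists did not pass. The acrosome list, genes of the sperm's enzyme cap that round spermatids build, had 20 of 31 members higher (adjusted p = 0.118): Acrv1 averaged 205 ± 25.8 FPKM in young and 225 ± 18.0 FPKM in aged samples and Spaca1 217 ± 27.1 and 242 ± 28.6 FPKM (SD, n = 5). The late spermatid list had 20 of 28 members lower (adjusted p = 0.155), the meiosis list 20 of 28 (adjusted p = 0.0613; Sycp3, of the synaptonemal complex, 87.5 ± 10.2 and 72.3 ± 9.59 FPKM) and the spermatogonial list 6 of 12 (adjusted p = 0.654). Single libraries changed these calls. The acrosome list passed without young replicate 5 (0.0350), in which Spink2, a member of the list, stood at 737 FPKM against at most 28.9 FPKM elsewhere. The late spermatid list passed without young replicate 2 (0.0039) or 3 (0.0425) or aged replicate 1 (0.0248). The meiosis list passed without young replicate 5 (0.0335) or aged replicate 4 (0.0072) or 5 (0.0294). Other settings changed them too: the acrosome and meiosis lists passed with voom (0.0335 each), the acrosome list over genes with a mean of at least 5 FPKM (0.0436), and the meiosis list with no filter on low values (0.0241).

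Cytosolic ribosomal protein genes were slightly higher in aged samples by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.573). Of 78 members 60 were higher, with a median log2 difference of 0.09. Rplp0 averaged 279 ± 13.9 FPKM in young and 293 ± 17.8 FPKM in aged samples (SD, n = 5), and Rps6 2.76 ± 0.250 and 2.61 ± 1.02 FPKM; many of these genes have near-identical copies in the genome, so single values are uncertain. The adjusted p was 7.27e-06, 0.573 with an estimated correlation and 0.0742 with the somatic score as a covariate. Nuclear genes of oxidative phosphorylation had 46 of 61 members higher, with a median of 0.05 (adjusted p = 0.0018, and 0.573 with an estimated correlation); Cox4i1 averaged 346 ± 2.85 and 352 ± 39.0 FPKM and Ndufs1 60.4 ± 4.40 and 56.8 ± 3.30 FPKM. This call was lost without aged replicate 5 (0.118). Transcripts of the mitochondrial genome did not pass (adjusted p = 0.155), with 10 of 11 lower and a median of -0.12; Mt-co1 averaged 1001 ± 110 and 902 ± 162 FPKM. Single libraries decided this result: the adjusted p was 0.0306 without young replicate 2, 0.0031 without aged replicate 2 and 0.0113 without both aged replicates 1 and 2, but 0.994 without aged replicate 5, whose score (-0.45) was the lowest. With the somatic score as a covariate it was 0.000585, again by camera with the preset correlation. No member of these 3 lists passed over all genes or adjusted over the list alone.

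The remaining lists did not pass. DNA methylation and histone modifier genes had 46 of 70 members lower (adjusted p = 0.0821; Dnmt1 1.39 ± 0.307 and 1.65 ± 0.314 FPKM, Dnmt3a 1.29 ± 0.195 and 1.47 ± 0.293 FPKM), and passed without young replicate 5 (0.0455) or aged replicate 4 (0.0236) and with no filter on low values (0.0250). Apoptosis and senescence genes had 14 of 23 members higher (adjusted p = 0.155; Bax 0.947 ± 0.228 and 1.61 ± 0.352 FPKM). Heat shock and chaperone genes (0.723, 17 of 43 higher), the proteasome (0.409, 21 of 39), autophagy and lysosome (0.367, 20 of 35), glycolysis (0.752, 9 of 24), cholesterol synthesis (0.767, 9 of 21) and the unfolded protein response (0.928, 10 of 24) had adjusted p values above the threshold. For glycolysis the median was -0.02 and the mean 0.05, and for the unfolded protein response -0.02 and 0.01, so that median and test differed in sign. Of the 28 lists, 12 passed with the preset correlation, 9 higher and 3 lower, and 0 with an estimated correlation or with fry. With the somatic score as a covariate, 2 lists passed with the preset correlation. Of these, oxidative phosphorylation (0.0017) was among the 12 and mitochondrial transcripts were not. Over libraries the oxidative phosphorylation shift with this covariate was 0.088 (SE 0.047), under 2 SE. In the main fit the estimated correlation was 0.139 for this list and 0.737 for mitochondrial transcripts, above the preset 0.01. These 2 calls were not tested with an estimated correlation. Compared as list scores per library, no list passed after adjustment (lowest adjusted exact permutation p = 0.111). That value belongs to the Leydig cell and immediate-early lists, in which all 5 aged libraries scored above every young library. Such complete separation gives the smallest p this permutation test can reach (0.00794 before adjustment). As even complete separation did not pass over the 28 lists, no conclusion is drawn from the lack of calls.

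Genes on chromosome X were higher in aged round spermatids by camera with the preset correlation (p = 2.09e-08), but not with an estimated correlation (p = 0.0825). X-linked transcription is silenced during male meiosis and only partly resumed in spermatids. The 396 tested X genes had a median log2 difference of 0.08 and the 12529 autosomal genes -0.02, a difference of 0.10, and 69.9% of X genes against 44.7% of autosomal genes were higher. At an unadjusted p under 0.05, 59 X genes were higher and 9 lower. Beside Pin4 and Nkap, chosen after their values were seen, Rai2 averaged 5.76 ± 0.887 FPKM in young and 7.54 ± 0.138 FPKM in aged samples and Bcor, a transcriptional corepressor, 5.89 ± 0.300 and 6.79 ± 0.207 FPKM (SD, n = 5). Some of the 59 had larger differences with a wide aged spread, also chosen after their values were seen. Bgn, a member of the peritubular list, averaged 1.54 ± 0.62 and 7.23 ± 7.32 FPKM, and Flna 2.86 ± 0.92 and 7.24 ± 4.30 FPKM.

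Adjusted over all chromosomes tested, the camera p for chromosome X was 4.81e-07, and 0.913 for each of the others. Per library, the X minus autosome difference lay between -0.14 and 0.06 in young and between -0.04 and 0.09 in aged samples (exact permutation p = 0.0556), so that the groups overlapped. Without aged replicates 1 and 2 the difference was 0.08.

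**Figure D2:**
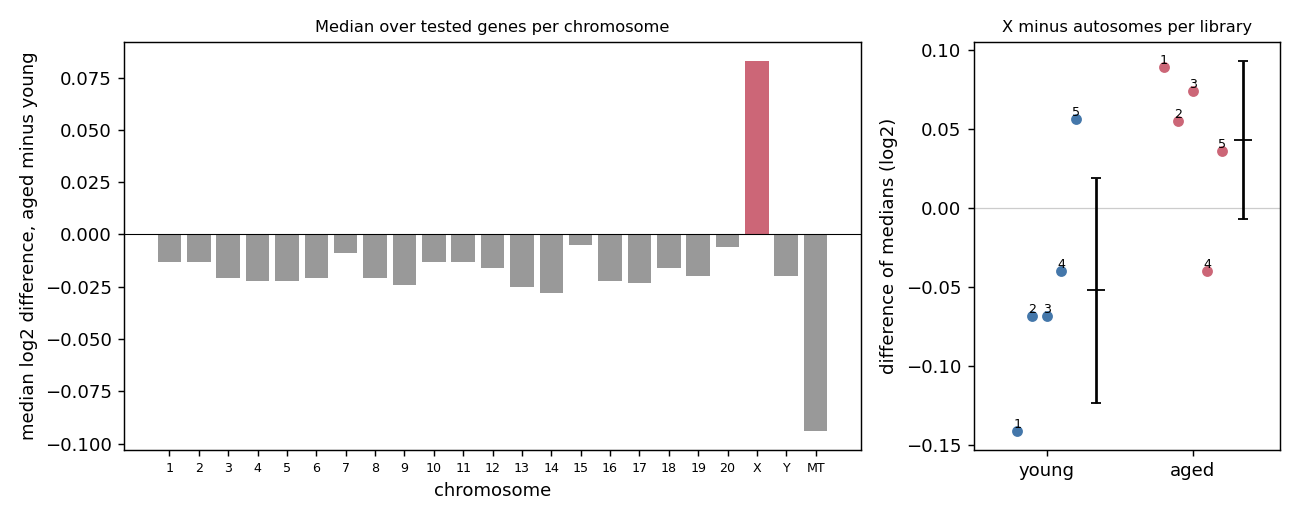
Median log2 difference between aged and young samples over the tested genes of each chromosome (left, bars from 0), and the X minus autosome difference of medians per library (right, log2, with the replicate number beside each point and bars for the mean and SD). Chromosome X stands at 0.083, and the aged libraries lie between -0.040 and 0.089.

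Over the tested genes as a whole, no difference in the spread between samples was found between the ages. The SD was larger in the aged group for 51.6% of the tested genes (exact permutation p = 0.818), and over all splits of the 10 libraries that share ran from 28.4% to 71.6%. Such a share cannot show a spread confined to some genes. The somatic score had an SD of 0.153 among young and 0.557 among aged libraries, aged replicate 2 being the highest. For the acrosome score the SDs were 0.129 and 0.056. These SDs of scores were not tested.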

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

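A library was singled out here where its gap to the nearest library of its group was a large part of the group's range (Dixon's test). Of 222 groups of 5 values tested, 17 were singled out, where chance gives about 11. The tests of gene length, of the somatic covariate on chromosome X and of RNA from other cells were chosen after the result was seen, as were the tests without aged replicates 1 and 2 and of the spermatocyte share on the repair and piRNA lists. The test of the spermatocyte share on chromosome X was not among the alternatives fixed in advance either. All tests of a shift below are on scores per library.

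Aged replicate 2 was the highest aged library for the Sertoli cell score (0.791, the others up to 0.076), the autophagy and lysosome score (0.333), Tpm2 (4.112 on the log2(FPKM + 1) scale), Csrp1 (4.781), Nr4a1 (4.082), Vim (5.337), Kit (2.0) and Acta2 (6.477). These go with the pattern of markers of other testis cells and immediate-early genes. RNA of other testis cells in the spermatid fraction, which STA-PUT separation reduces, is a candidate explanation: in 6 of the 7 somatic lists the median over members with at least 0.1 FPKM was higher in aged samples by over 0.2, the lymphocyte list (0.029) being the exception and the endothelial (0.762) and erythroid (0.827) lists among the 6, and with the somatic score as covariate the immediate-early shift was 0.036 (SE 0.043) against 0.636 (SE 0.266) before. The first of these tests is weak, since 4 of the lists had been seen higher before it and a rise of these genes within the spermatids would give the same. The second cannot tell sources apart either, as the somatic score was highest in aged replicates 2 (1.21) and 1 (0.43). A list high in those libraries can lose its shift with this covariate whatever the source, as the antioxidant list did (0.252 before and -0.007 with it). Among abundant markers, Apoe ran from 22.9 to 280 FPKM in aged and from 8.08 to 28.2 FPKM in young libraries, and Insl3 from 5.82 to 86.4 and from 2.31 to 4.03 FPKM, aged replicate 2 being the highest for both. Without aged replicates 1 and 2 the somatic score still differed by 0.238 (SE 0.098), against 0.589 (SE 0.259) with them. That remainder is only a little over 2 SE in few libraries, and aged replicate 3 (-0.15) lay below young replicate 5 (-0.056). These libraries alone are therefore not excluded as the source of the pattern. Of the list members, 14 of 30 Sertoli cell, 13 of 20 peritubular, 7 of 26 macrophage and 5 of 20 Leydig cell genes were above 1 FPKM in every young library, and a change with age within the spermatids stays open, as untested.

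The X-linked shift was 0.095 (SE 0.039) as a score per library. A length and level trend does not account for all of it (0.077 after removal, SE 0.038, only just beyond 2 SE). With the acrosome minus meiosis score as covariate, a measure of the share of spermatocytes against round spermatids, it was 0.064 (SE 0.014). Both values are smaller than 0.095. The acrosome list holds Spink2, at 737 FPKM in young replicate 5 and at most 28.9 FPKM elsewhere, and its score was highest in that library (0.186). The stage score may thus follow 1 gene of 1 library, so it cannot decide on the share of spermatocytes. RNA of other cells and an X-linked change cannot be told apart, because with the somatic score as covariate the shift was 0.068 with an SE of 0.051. Camera with the preset correlation still called chromosome X with that covariate (difference 0.066, p = 0.00029). Without the covariate that call was not kept with an estimated correlation. Of 100 splits of the 10 libraries, 3 including the real one gave a median difference at least as large in size as the real 0.10, the highest other being 0.148, but the exact permutation p of the score per library was 0.0556 and camera with an estimated correlation gave a p of 0.0825, so these tests together do not exclude chance. An effect of age on the X chromosome stays open and was not tested apart from these.

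The ribosomal and oxidative phosphorylation lists, of short genes, were higher and the repair, axoneme and piRNA lists, of long genes, lower, but mitochondrial transcripts, also short (median 684 bp), had 10 of 11 members lower; log2 differences correlated with gene length across genes (Spearman's rho -0.118; genes are not independent replicates). With the length and level trend removed, double-strand break and mismatch repair kept its shift (-0.102, SE 0.038, against -0.103 before), so length does not account for it. With the acrosome minus meiosis score as covariate the repair shift was -0.076 (SE 0.017), smaller than before. As that score holds Spink2, it cannot decide here either on the share of spermatocytes. For the piRNA list (-0.051, SE 0.049) that share and other sources cannot be told apart. The axoneme shift went to -0.016 (SE 0.018) from -0.044 (SE 0.022), which a length trend may explain. For the ribosomal list (0.106, SE 0.056, against 0.119, SE 0.053, before) and oxidative phosphorylation (0.069, SE 0.037, against 0.084, SE 0.034) most of the shift was left. Camera with the preset correlation still called them (adjusted p = 0.000373 and 0.0360). In the main fit, however, an estimated correlation kept neither call (0.573 each), and the shifts left lay under 2 SE over libraries. For the piRNA list (-0.067, SE 0.059) the shift was under 2 SE already before (-0.085, SE 0.060). For these lists length and other sources, an effect of age among them, cannot be told apart.

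Other libraries apart from their group were young replicate 4 for the apoptosis and senescence score (-0.082), young replicate 1 for the share of non-coding fragments (2.02%), Acrv1 (7.332) and Catsper1 (5.092), young replicate 3 for Lctl (3.235), aged replicate 1 for Tnp1 (12.75) and Cd3g (1.709), aged replicate 3 for Cdkn1a (0.8934) and aged replicate 5 for Spaca1 (8.193).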

How the results depend on the processing

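The fits without aged replicates 1 and 2, with a covariate, or with a length trend removed were chosen after seeing the data, as were the tests of single lists under other filters, TPM or quantile scaling, protein-coding genes, robust eBayes, sample weights and voom. No gene passed under any setting run on all 10 samples, and leaving out 1 sample gave 0 to 1. The genes at an unadjusted p under 0.05, 1544 with the main settings, numbered 2379 with no filter and 887 at a mean of at least 5 FPKM (more and fewer genes tested), 972 without aged replicates 1 and 2 (fewer samples), and 630 with the somatic score as covariate. Over all tested genes the replicate numbers did not pair the samples: the correlations of same-numbered samples were -0.141, -0.158, 0.010, -0.018 and 0.054, although Spag4, Pfkfb4 and Polr2i, unlike Gsto2 and Spink2, stood apart in the same numbers at both ages. With the replicate block, 0 genes and 12 lists passed, and the X difference was 0.10. Only young replicate 3 correlated best with its own number. The X difference depended on the filter: it was 0.114 at a mean of at least 5 FPKM, 0.074 at 0.1 FPKM and 0.04 with no filter. Leaving out 1 sample gave 0.075 to 0.125. Over the alternatives 1816 of 1857 comparisons of the 75 named genes kept their direction and their side of the threshold, and 41, over 24 genes, did not keep their direction. The alternatives include median-of-ratios scaling, which gave the same 1544 genes, 12 lists and smallest adjusted p (0.281) as the main settings, so it was no separate check. Changes of direction or call whose cause is not stated here were not tested for their cause. Depth limits low genes most: 1 FPKM over 1 kilobase stands for 14.6 fragments in the shallowest library.

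With the main settings 12 lists passed, with an estimated correlation 0 and with fry 0. With an estimated correlation the adjusted p was 0.5726 for the Sertoli cell, Leydig cell, peritubular, macrophage, antioxidant, double-strand break repair, ribosomal, oxidative phosphorylation and immediate-early lists, 0.6184 for piRNA and inflammation, and 0.6688 for the axoneme; for chromosome X the difference stayed 0.10 and the p was 0.0825. With fry it was 0.2859 for Leydig cell, peritubular, double-strand break repair and immediate-early, 0.3742 for Sertoli cell, macrophage, antioxidant, ribosomal and axoneme, 0.3841 for oxidative phosphorylation and piRNA, and 0.4138 for inflammation; lymphocyte (0.973) and the unfolded protein response (0.8518) changed direction. Without aged replicates 1 and 2 the adjusted p was 0.1909 for axoneme, 0.9003 for piRNA and 0.3096 for inflammation, mitochondrial transcripts passed (0.0113), and lymphocyte (0.9553), heat shock (0.5667) and the unfolded protein response (0.9553) changed direction.

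With the somatic score as covariate and the preset correlation 2 lists passed, oxidative phosphorylation (0.00174) and mitochondrial transcripts (0.0005854). The oxidative phosphorylation score shift was then 0.088 (SE 0.047), under 2 SE over libraries. The adjusted p was 0.07415 for peritubular, double-strand break repair and ribosomal, 0.4417 for Leydig cell and immediate-early, and 0.9641 for antioxidant, axoneme and piRNA. Direction changed for Sertoli cell and macrophage (0.5015 each), inflammation (0.6225), lymphocyte (0.6287), heat shock (0.696), apoptosis (0.9641), autophagy (0.4417) and the unfolded protein response (0.6542). The somatic lists lose their calls by construction, as the score is made of their members: the peritubular median went from 0.827 to 0.094. The repair median stayed nearer, at -0.085 against -0.104, and its score shift went from -0.103 (SE 0.036) to -0.068 (SE 0.044), so its call ended with a smaller shift and a wider spread; the ribosomal median was 0.048 against 0.094. With the length trend removed acrosome passed (0.04802), axoneme (0.7105), piRNA (0.1824) and inflammation (0.06257) did not, and lymphocyte (0.9254) and heat shock (0.8171) changed direction.

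With a mean of at least 0.1 FPKM, meiosis and DNA methylation and histone modifiers passed (0.04205 each) and cholesterol synthesis changed direction (0.886). With no filter the same lists passed (0.02408 and 0.02502), and cholesterol synthesis (0.8631) and lymphocyte (0.7123) changed direction. At a mean of at least 5 FPKM acrosome passed (0.04355), macrophage (0.8141), axoneme (0.1086) and piRNA (0.1122) did not, and glycolysis (0.8857), autophagy (0.8141) and the unfolded protein response (0.8557) changed direction. After TPM scaling axoneme (0.1305), piRNA (0.05246) and inflammation (0.05246) did not pass, nor after quantile scaling (0.08304, 0.05823 and 0.06597), where heat shock changed direction (0.9967). With sample weights piRNA did not pass (0.05601), and late spermatid (0.7742), lymphocyte and heat shock (0.8819 each) changed direction. With voom acrosome and meiosis passed (0.03345 each) and axoneme (0.1472) and inflammation (0.05966) did not.

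Leaving out 1 sample at a time gave adjusted p ranges of 0.0350 to 0.4785 for acrosome, 0.003864 to 0.6554 for late spermatid, 0.007236 to 0.2077 for meiosis, 0.2886 to 0.9347 for spermatogonia, 0.6032 to 0.9863 for lymphocyte, 0.4423 to 0.8686 for heat shock, 0.0001447 to 0.1178 for oxidative phosphorylation, 0.003133 to 0.9942 for mitochondrial transcripts, 0.3186 to 0.9998 for glycolysis, 0.004011 to 0.1342 for axoneme, 0.002399 to 0.2393 for piRNA, 0.02361 to 0.2188 for DNA methylation and histone modifiers, 0.007808 to 0.1208 for inflammation, 0.4248 to 0.9272 for cholesterol synthesis and 0.4983 to 0.9847 for the unfolded protein response. The 8 other lists past the threshold stayed past it in each of these fits. The share of genes with a larger SD in aged samples ran from 47.86% to 60.49%, was 49.24% at a mean of at least 5 FPKM, and 43.08% without aged replicates 1 and 2.

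After quantile scaling Prm1 came to 0.000, which the scaling fixes because it ranks 1 in every library. Named genes that changed direction, none of which passed in any setting, were Tnp1 at 0.038 after quantile scaling and Catsper1 at -0.033 with sample weights. Without aged replicates 1 and 2 they were Wt1 (-0.093), Cd74 (-0.348), Cd3d (0.057), Ldhc (0.024), Catsper1 (-0.014) and Piwil1 (0.029). With the somatic covariate they were Kit (-0.140), Clu (-0.338), Wt1 (-0.166), Cd74 (-0.658), Cd163 (-0.139), Cd3d (0.111), Psma1 (-0.015), Dnmt1 (-0.015) and Jun (-0.039). With the length trend removed they were Wt1 (-0.008), Cox4i1 (-0.002), Ddx4 (0.001) and Map1lc3a (-0.007). Leaving out 1 sample gave -0.076 to 0.040 for Catsper1, -0.081 to 0.457 for Cd74, -0.040 to 0.058 for Cox4i1, -0.003 to 0.131 for Gpx4, -0.001 to 0.052 for Hspa2, -0.053 to 0.057 for Map1lc3a, -0.010 to 0.072 for Map1lc3b, -0.180 to 0.006 for Mt-nd1, -0.109 to 0.004 for Ogg1, -0.006 to 0.036 for Psmc3, -0.179 to 0.014 for Tnp1, -0.026 to 0.120 for Wt1 and -0.088 to 0.007 for Xpc.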

Other observations

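The test of splits on the genes past the threshold was chosen after the result was seen. Several genes were nearly on or off from one library to the next within the same age group. The genes were chosen after their values were seen, 5 of the 10 with the widest SD among young libraries of the 7823 genes with a mean of at least 5 FPKM. Spag4, a gene of the spermatid nuclear envelope and flagellum, stood at 3.99 FPKM in young replicate 1 and 3.23 FPKM in aged replicate 1, and between 63.2 and 175 FPKM in the other 8 libraries. Spink2, a protease inhibitor of the acrosome, was at 737 FPKM in young replicate 5 and between 15.0 and 28.9 FPKM elsewhere. Pfkfb4, a regulator of glycolysis, was at 20.13 to 20.96 FPKM in young replicates 4 and 5 and at 10.02 to 11.01 FPKM in aged replicates 4 and 5, and at most 1.11 FPKM in the other libraries. Polr2i was at 33.3 FPKM in young replicate 3 and 47.3 FPKM in aged replicate 3, and at most 0.514 FPKM elsewhere. Gsto2 ranged from 3.62 to 95.2 FPKM among young and from 3.11 to 68.0 FPKM among aged libraries. The median gene of this set had an SD of 0.113 among young and 0.108 among aged libraries on the log2 scale, and the SD of Spag4 was 2.09 and 2.27. For Spag4, Pfkfb4 and Polr2i the libraries that stood apart had the same replicate numbers at both ages, and the labels do not say what these numbers share. Other genes did not follow this. Gsto2 was high in young replicates 1 and 4 (67.8 and 95.2 FPKM) but in aged replicates 2 and 5 (48.3 and 68.0 FPKM). Spink2 was high in young replicate 5 only. Sepw1, another of the 10, was highest in young replicate 3 (119 FPKM) and aged replicate 2 (127.5 FPKM). No explanation was tested.

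AC117925.6, a protein-coding gene on chromosome 4 (114850815 to 114853868, minus strand, as the files give it), had the lowest fitted log2 difference among the genes tested, -3.08 (SE 0.85, limma adjusted p = 0.319). It stood between 51.8 and 88.3 FPKM in 4 young libraries, at 2.18 FPKM in young replicate 2 and between 1.36 and 12.6 FPKM in the aged libraries.

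Other splits of the 10 libraries were fitted to see how often they give results as large. For genes past the threshold the comparison says nothing, since any split gives at least the 0 of the real one (100 of 100, with 2 as the highest other). For genes at an unadjusted p under 0.05, 3 of 100 splits, the real one included, gave at least its 1544, and the others gave 2071 and 2560. This share is small, but splits that mix the ages gave more genes than the real one, and the tests of splits were not adjusted for their number. Chance is therefore not excluded for that count, which was 972 without aged replicates 1 and 2 and 630 with the somatic score as covariate. For the fixed lists, 22 of 100 splits gave at least 12 lists past the preset test, with 15 as the highest other, so chance cannot be excluded for the number of lists.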
